A study of Arabidopsis thaliana with 12 samples.

How the data were processed

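RNA sequencing was carried out on Arabidopsis seedlings of 4 genotypes, wild-type Col-0 and the mutants gun1-1, gun4-1 and gun5-1, with 3 biological replicates each and 12 libraries in all. Per the labels, all were grown for 5 days at 100 µE with 5 µM norflurazon. The sample labels give whole seedlings as the source, while the design text speaks of leaf RNA. The labels describe oligo(dT) selection of mRNA and random-hexamer priming. They also mention a piperonylic acid treatment of gun5-1, which none of the 12 libraries carries. Trimmomatic, TopHat, Cufflinks and Cuffdiff are named per the labels. Their versions, the genome build and the annotation release are not given in the sources used here.

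The 3 deposited tables each compare 1 mutant with Col-0 and hold 64480 transcripts of 38093 genes. Each gives group FPKM values (fragments scaled by transcript length and by mapped fragments) as the authors' Cuffdiff made them. The deposited log2 fold change is the mutant over Col-0. The deposited test score is Cuffdiff's signed statistic. The deposited p-value and q-value are Cuffdiff's, the q-value being adjusted over all tested transcripts. The tables hold no values per library, so depth is unknown and no spread between replicates could be computed. The authors' scaling differed between tables: Col-0 values in the gun4-1 and gun5-1 tables were 1.07 and 0.984 times those in the gun1-1 table. Coordinates are those of the deposited tables, with 1 added to the start, and span all transcripts that overlap at a place. The reference annotation served for gene names and, in a search made after the data were seen, for the genes of process terms.

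Each gene was represented by its transcript with the highest mean FPKM. A gene was called higher or lower where the authors' test had status OK and a q-value under 0.05; genes with another status were untested. The standard error of a log2 fold change was taken as its ratio to the test statistic, or as its ratio to the normal quantile of the p-value where that was larger and the p was above the smallest listed, 5e-05. Errors given as SE are these. Medians of log2 fold changes leave out genes listed at 0 in a group, whose fold change is infinite.

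Before the data were examined, 20 gene lists with 298 genes were fixed, and the genes of the plastid and mitochondrial genomes formed 2 further lists. The planned list test was limma's cameraPR on the authors' statistics of all tested genes, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 66 tests. The correlation could not be estimated from group values. In each table a few very short transcripts had a large statistic with a large p: 19, 18 and 14 genes in gun1-1, gun4-1 and gun5-1 had a statistic above 5 in size with p above 0.01. These widen the spread on which the planned test rests. The same test on ranks of the statistics was therefore added after the data were seen, and both are given. In 100 simulated sets of 18000 genes, the planned test called 99 of 100 lists with a planted shift at an unadjusted 0.05. It called 59 of 2000 unchanged lists. The simulated statistics were independent normal values, without correlated genes or statistics that disagree with their p. These counts therefore do not gauge the planned test on the present data.

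For differences between mutants, the difference of the log2 fold changes was divided by the root of the sum of squared SE, with a two-sided normal p and Benjamini-Hochberg adjustment over genes tested in both tables. The plan made this test conditional on SE that match the deposited p-values. They did not match: the deposited p corresponded to statistics about 1.73 times larger in each table. The test was run nevertheless, with the larger SE, and counts as chosen after the data were seen. On simulated data with those SE it recovered 33 of 67, 43 of 66 and 34 of 61 changes of 2 on the log2 scale. It recovered at most 13 of 74 changes of 1 and none of 0.5, with 0 false calls. The simulated noise was drawn from the same SE with a shared control, so few false calls were built in. These counts do not gauge errors or sensitivity on the deposited values. Differences between mutants in the fixed lists were tested by cameraPR on these z values, with a correlation of 0.01 and 66 tests. This test was not in the plan, and was also run on ranks and with a correlation of 0.05. At adjusted p under 0.05 the 4 versions gave 36 (z, 0.01), 30 (z, 0.05), 28 (ranks, 0.01) and 25 (ranks, 0.05) list differences, of which 24 passed in every version.

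Overlaps of calls were set beside those of independent lists and 100 simulations of unchanged mutants that share control libraries. Correlations of log2 fold changes used genes with FPKM of at least 5 in Col-0 and both mutants and without the disagreeing statistics, a filter chosen after the data were seen.

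Genes named in the text followed a rule fixed before the data were examined: the 3 mutated genes; 12 genes of photosynthesis, tetrapyrrole and anthocyanin synthesis and their regulation; up to 3 called genes with the largest change from each list; and the 5 largest rises and falls among called genes with FPKM of at least 5 and a symbol. For differences between mutants, the 5 largest in each direction were taken the same way. Alternatives were a q threshold of 0.01, a minimum absolute log2 fold change of 1, a minimum of 1 FPKM, median centring, a pseudocount of 1 FPKM and an inter-gene correlation of 0.05. Further alternatives were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.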

Results

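Transcript levels were measured by RNA sequencing in 5-day-old Arabidopsis seedlings grown on norflurazon, an inhibitor of carotenoid synthesis that bleaches plastids in the light. Wild-type Col-0 was compared with gun1-1, gun4-1 and gun5-1, mutants of plastid-to-nucleus signalling, with 3 libraries per genotype. GUN1 is a plastid pentatricopeptide repeat protein, GUN4 a regulator of magnesium chelatase and GUN5 its H subunit, CHLH. Values in the authors' deposited tables are group FPKM of n = 3 libraries, so spread between replicates and depth are unknown. All mutants were on norflurazon, and each was compared with Col-0 on norflurazon. Genes are called higher or lower by the authors' q under 0.05, and list tests give adjusted p from limma's camera on the authors' statistics, followed by the same test on ranks. The rank test was added after the data were seen, because statistics of a few very short transcripts reached 738 in size, with a p of 0.508 by the authors' test.

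The first comparison asks which transcripts differ in gun1-1. Nuclear photosynthesis genes were higher throughout: 20 of 20 light-harvesting genes, 27 of 27 photosystem and electron transport genes and 21 of 21 Calvin cycle genes, with the same counts adjusted over the list alone. By the authors' deposited table, LHCB1.1 (AT1G29920) went from 33.5 to 2075 FPKM, a log2 fold change of 5.95 (SE 0.19), LHCB1.4 (AT2G34430) rose by 6.86 (SE 0.60) and LHCB2.2 (AT2G05070) by 5.63 (SE 0.20). LHCB1.2 (AT1G29910) rose by 3.64 (SE 0.18). Members of the LHCB1 and RBCS families have near-identical sequences, so the split between them is uncertain. CA1 (AT3G01500), a plastid carbonic anhydrase, rose by 7.70 (SE 0.29), RBCS2B by 4.94 (SE 0.19), CP12-2 by 3.29 (SE 0.18) and RBCS1A by 1.31 (SE 0.26). PSBQ2 rose by 4.02 (SE 0.19), PETE1 by 3.73 (SE 0.27) and PSBS by 3.38 (SE 0.18). The list tests gave adjusted p = 8.39e-21 for light harvesting, 2.37e-14 for the photosystem list and 2.13e-11 for the Calvin cycle, and 1.03e-11, 2.09e-14 and 8.83e-12 on ranks.

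Of 30 tetrapyrrole genes, 23 were higher and 1 was lower in gun1-1 (25 and 1 adjusted over the list alone). HEMA1 (AT1G58290), the first enzyme of the pathway, rose by 1.91 (SE 0.17), HEMF1 by 1.76 (SE 0.17) and CHLH (AT5G13630) by 1.75 (SE 0.19). The list test gave adjusted p = 0.0226 (1.25e-09 on ranks), and adjusted p = 0.199 with the correlation set to 0.05. Of 16 carotenoid genes 15 were higher, also adjusted over the list alone, among them BCH2 by 4.05 (SE 0.72), PSY by 1.80 (SE 0.36) and BCH1 by 1.70 (SE 0.17). That list missed the planned threshold (adjusted p = 0.0933) and passed on ranks (1.89e-07). Of 12 chloroplast regulators, 9 were higher and 1 was lower (adjusted p = 0.177, on ranks 0.00197). GLK1 (AT2G20570), a transcription factor of photosynthesis genes, rose by 2.2998 (SE 0.32), GLK2 by 1.82 (SE 0.21) and SIG1 by 1.77 (SE 0.18). All 7 plastid chaperone genes were higher (adjusted p = 0.222, on ranks 2.55e-04), led by CPHSC70-2 at 1.39 (SE 0.16), CLPB3 at 1.01 (SE 0.18) and CPHSC70-1 at 0.88 (SE 0.17). GUN1 itself (chromosome 2, 13386954 to 13390854, build not given) had 149 FPKM in Col-0 and 137 in gun1-1, a change of -0.12 (SE 0.16) that did not pass. GUN4 (AT3G59400) lay near 2 FPKM in Col-0 in a span shared with a neighbouring gene and did not pass in any of the 3 mutants.

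Anthocyanin enzymes were lower in gun1-1. Of 11 late anthocyanin genes, 6 were lower and 1 was higher (7 and 1 adjusted over the list alone), and of 8 early flavonoid genes, 7 were lower. LDOX (AT4G22880) fell by 2.29 (SE 0.63), DFR (AT5G42800) by 2.21 (SE 0.31) and UGT79B1 by 1.74 (SE 0.33), and of the early genes FLS1 fell by 1.26 (SE 0.17), UGT78D1 by 1.16 (SE 0.19) and CHS (AT5G13930) by 1.09 (SE 0.18). These lists missed the planned threshold (adjusted p = 0.484 and 0.222) and passed on ranks (0.00344 and 7.41e-04). Of 15 flavonoid regulators, 7 were higher and 5 lower (adjusted p = 0.955, on ranks 0.752). PAP1 (AT1G56650), an activator of anthocyanin genes, fell by 1.02 (SE 0.53), MYB11 by 1.15 (SE 0.51) and SPL9 by 0.98 (SE 0.64). TT8 rose by 0.77 (SE 0.27) and MYBL2, a repressor, by 0.96 (SE 0.19). HY5 gave -0.13 (SE 0.19) and did not pass, and PAP2 was untested. Of 6 phenylpropanoid genes, 2 were higher and 3 lower (adjusted p = 0.884, on ranks 0.279), with PAL4 at -1.74 (SE 0.47), 4CL3 at -1.25 (SE 0.20) and PAL2 at 0.51 (SE 0.17).

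Plastid-encoded transcripts moved the other way from nuclear photosynthesis genes in gun1-1: 39 of 58 were lower and 0 higher (45 lower adjusted over the list alone), with a median log2 fold change of -1.67. ndhC fell by 2.26 (SE 0.59), and psbK and psaJ, at 129 and 2373 FPKM in Col-0, were listed at 0 in gun1-1. Finite plastid changes in gun1-1 went no lower than -2.44, so these zeros stand apart and are not read as loss of the transcripts. The list test gave adjusted p = 0.00307 (1.049e-15 on ranks) and 0.116 with the correlation set to 0.05. Of 11 mitochondria-encoded genes 1 was higher, ATMG01390 by 0.49 (SE 0.17), and the list missed both tests (adjusted p = 0.928 and 0.148). Of 10 heat-shock genes 6 were higher and 0 lower (7 higher adjusted over the list alone), HSP17.6II by 2.95 (SE 0.99), HSP17.6A by 2.75 (SE 0.30) and HSP70 (AT3G12580) by 2.74 (SE 0.17). Their list test gave adjusted p = 0.0933, and 8.94e-04 on ranks.

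Among the other lists in gun1-1, 11 of 13 seed storage and maturation genes were lower (adjusted p = 0.162, on ranks 1.78e-06), including SESA4 at -3.08 (SE 1.65), EM1 at -2.44 (SE 0.60) and CRA1 at -2.26 (SE 0.23). The oxidative stress list had 6 of 19 genes higher and 6 lower (adjusted p = 0.928 and 0.788 on ranks): CAT3 fell by 1.81 (SE 0.17) and UPOX by 0.95 (SE 0.17), and CAT2 rose by 1.12 (SE 0.20). Of 8 root markers 4 were lower (adjusted p = 0.830, on ranks 0.0113), EXPA18 by 0.70 (SE 0.25), RSL4 by 0.57 (SE 0.38) and COBL9 by 0.49 (SE 0.31). Of 12 genes of the plastid RNA polymerase complex, 4 were higher and 5 lower (adjusted p = 0.943 and 0.572), with PTAC6 up by 0.75 (SE 0.20), PTAC7 up by 0.64 (SE 0.17) and FSD2 at -0.68 (SE 0.25). Clock genes were higher in 5 and lower in 2 of 11 cases (adjusted p = 0.914 and 0.216), CCA1 by 1.18 (SE 0.26), GI by 1.01 (SE 0.20) and PRR7 by 0.78 (SE 0.27). Single genes passed in the sugar starvation list (GPT2, -1.31, SE 0.62, 1 of 9; adjusted p = 0.928, on ranks 0.833), the jasmonate and salicylate list (JAZ10, 1.22, SE 0.75, 1 of 7; 0.928 and 0.667) and the glucosinolate list (CYP83B1, -0.69, SE 0.21, 1 of 5; 0.928 and 0.261). Over all genes, CYP706A6 rose by 6.13 (SE 0.62). Among called genes with a symbol, a finite fold change and 5 FPKM or more, the largest falls were FTM1 at -6.14 (SE 0.81), chr31 at -5.57 (SE 0.83), TIM17-1 at -5.42 (SE 1.80), MEE66 at -5.04 (SE 0.99) and ALPHA-VPE at -3.46 (SE 1.04). In all, 6336 of 18776 tested genes were called in gun1-1, 3537 higher and 2799 lower, of which 1099 and 662 changed at least 2-fold.

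The comparison with gun4-1 asks the same for the chelatase regulator. Nuclear photosynthesis genes were higher here too: 19 of 20 light-harvesting genes, 26 of 27 of the photosystem list and 19 of 21 Calvin cycle genes (19, 26 and 21 adjusted over the list alone). By the authors' deposited table, LHCB1.4 and LHCB1.1 each rose by 3.16 (SE 0.63 and 0.19), LHCB1.2 by 2.60 (SE 0.18), CA1 by 4.61 (SE 0.28), RBCS2B by 1.35 (SE 0.19) and RCA, Rubisco activase, by 1.1007 (SE 0.32). PSBQ2 rose by 1.88 (SE 0.20), PSBS by 1.37 (SE 0.17) and PETE1 by 1.29 (SE 0.30). RBCS1A gave 0.46 (SE 0.35) and did not pass. The list tests gave adjusted p = 1.21e-05, 0.00531 and 0.00893 (1.43e-10, 1.50e-13 and 2.26e-11 on ranks). With the correlation set to 0.05, the photosystem and Calvin cycle lists both gave adjusted p = 0.0845.

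Tetrapyrrole genes were higher in 20 of 30 cases in gun4-1, also adjusted over the list alone (adjusted p = 0.219, on ranks 8.36e-09), HEMC by 1.26 (SE 0.17), PORC by 0.91 (SE 0.32) and HEMF1 by 0.89 (SE 0.18). HEMA1 rose by 0.50 (SE 0.17), CHLH by 0.69 (SE 0.19) and GUN1 by 0.35 (SE 0.17). Of 16 carotenoid genes, 5 were higher (adjusted p = 0.884, on ranks 0.0022), with PSY at 0.76 (SE 0.41), GGPPS11 at 0.39 (SE 0.18) and DXR at 0.38 (SE 0.18). Chloroplast regulators were mixed, 2 higher and 2 lower of 12 (adjusted p = 0.992, on ranks 0.660): RPOTMP fell by 1.13 (SE 0.35), RPOTP by 0.43 (SE 0.19), and GLK2 rose by 0.68 (SE 0.23). GLK1 gave 0.53 (SE 0.36) and did not pass.

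Late anthocyanin genes were lower in gun4-1 in 5 of 11 cases (7 adjusted over the list alone), with adjusted p = 0.472, and 7.41e-04 on ranks. LDOX fell by 1.81 (SE 0.63), DFR by 1.80 (SE 0.28) and UGT79B1 by 1.37 (SE 0.31). The early flavonoid list did not pass (adjusted p = 0.914, on ranks 0.115): F3PH fell by 1.28 (SE 0.25), CHI by 0.33 (SE 0.17), UGT78D1 rose by 0.36 (SE 0.18), and CHS gave -0.13 (SE 0.20). Of the regulators, PAP1 fell by 1.56 (SE 0.59), TT8 by 1.00 (SE 0.34) and MYB12 by 0.74 (SE 0.25), while MYBL2 at -0.14 (SE 0.20), HY5 at -0.18 (SE 0.19) and PAP2 at -1.13 (SE 1.11) did not pass. The list of 17 regulators had 1 higher and 3 lower (adjusted p = 0.928, on ranks 0.423). Of 6 phenylpropanoid genes 2 were higher, PAL2 by 0.52 (SE 0.17) and PAL1 by 0.31 (SE 0.17) (adjusted p = 0.928, on ranks 0.280).

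Plastid-encoded transcripts were higher in gun4-1: 42 of 66, with 0 lower (48 adjusted over the list alone) and a median of 1.64 (adjusted p = 1.403e-30, on ranks 1.049e-15). psaB rose by 3.07 (SE 0.39) and psaA by 2.85 (SE 0.36). psbH was listed at 0 in Col-0, again not read as absence, and at 28.5 FPKM in gun4-1. Mitochondria-encoded transcripts had a median of 1.2997, and 4 of 13 were higher (adjusted p = 0.472, on ranks 3.61e-05), among them ATMG01390 by 1.54 (SE 0.18), ATMG01360 by 1.34 (SE 0.51) and ATMG00090 by 0.99 (SE 0.37). Heat-shock genes were lower in 2 of 9 cases (1 higher and 5 lower adjusted over the list alone), HSP70 by 1.94 (SE 0.19) and HSP90.1 by 1.86 (SE 0.25), with adjusted p = 0.354 and 0.020 on ranks. The oxidative stress list had 8 of 19 lower and 1 higher (adjusted p = 0.616, on ranks 0.00339): FER1 fell by 1.37 (SE 0.21), UPOX by 0.99 (SE 0.18) and OXI1 by 0.82 (SE 0.32).

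Seed genes were lower in 4 of 13 cases in gun4-1 (adjusted p = 0.182, on ranks 1.91e-07), SESA3 by 2.49 (SE 0.58), and SESA2 and ABI3 both by 1.55 (SE 0.51 and 0.46). Plastid chaperones were higher in 3 and lower in 1 of 7 cases (adjusted p = 0.914, on ranks 0.0235), and 2 of 12 plastid polymerase genes were higher (adjusted p = 0.928, on ranks 0.138). Root markers were lower in 3 of 8 cases (adjusted p = 0.914, on ranks 0.0596) and clock genes in 2 of 11 (adjusted p = 0.914, on ranks 0.0611), including PRR7 by 0.84 (SE 0.33). Sugar starvation genes were higher in 1 and lower in 2 of 9 cases (1 and 4 adjusted over the list alone; adjusted p = 0.914, on ranks 0.0981): GPT2 was at -2.02 (SE 0.74), BCAT2 at -0.74 (SE 0.29) and STP1 at 0.29 (SE 0.17). ICS1 rose by 0.72 (SE 0.30), 1 of 8 in the jasmonate and salicylate list (adjusted p = 0.955, on ranks 0.621), and MYB28 by 1.92 (SE 0.60), 1 of 5 in the glucosinolate list (adjusted p = 0.928, on ranks 0.752). Over all genes, SADHU3-2 rose by 3.36 (SE 0.40), and M17 at -6.42 (SE 0.92), SESA5 at -6.06 (SE 0.80), FTM1 at -5.46 (SE 0.68), LCR67 at -4.17 (SE 0.52) and LEA at -3.77 (SE 1.26) fell most among genes so filtered. In all, 2680 of 18977 tested genes were called in gun4-1, 1561 higher and 1119 lower, and 301 and 276 changed at least 2-fold.

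The third comparison asks what differs in gun5-1. All 20 light-harvesting, 27 photosystem and 21 Calvin cycle genes were higher, also adjusted over the list alone. By the authors' deposited table, LHCB1.4 rose by 5.93 (SE 0.65), LHCB1.1 by 5.67 (SE 0.19), LHCB1.2 by 4.70 (SE 0.19), CA1 by 7.54 (SE 0.29), RBCS2B by 3.12 (SE 0.19), CP12-2 by 2.86 (SE 0.18) and RBCS1A by 1.60 (SE 0.29). PSBQ2 rose by 3.30 (SE 0.19), PETE1 by 2.77 (SE 0.29) and PSAO by 2.63 (SE 0.17). The list tests gave adjusted p = 1.04e-39, 1.71e-26 and 8.88e-25 (1.28e-11, 2.09e-14 and 6.02e-12 on ranks). Of 30 tetrapyrrole genes 26 were higher (26 higher and 1 lower adjusted over the list alone), CHLH by 1.85 (SE 0.19), HEMC by 1.72 (SE 0.17), CRD1 by 1.52 (SE 0.18) and HEMA1 by 1.46 (SE 0.17), with adjusted p = 6.39e-06 and 2.26e-11 on ranks. Of 16 carotenoid genes 15 were higher (16 adjusted over the list alone), BCH2 by 2.24 (SE 0.78), BCH1 by 1.61 (SE 0.17) and ZEP by 1.59 (SE 0.17), with adjusted p = 0.00375 and 6.61e-08 on ranks. Of 12 chloroplast regulators 9 were higher and 1 lower (adjusted p = 0.133, on ranks 0.00237), including SIG4 at 1.35 (SE 0.24), SIG1 at 1.23 (SE 0.18), SIG2 at 1.12 (SE 0.24) and GLK1 at 0.96 (SE 0.36). GUN1 rose by 0.68 (SE 0.17).

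Anthocyanin enzymes were lower in gun5-1, 8 of 11 late genes (9 adjusted over the list alone) and 7 of 8 early genes (8 adjusted over the list alone). DFR fell by 2.25 (SE 0.32), UGT79B1 by 2.03 (SE 0.38), GSTF12 gave -2.195 (SE 0.85), also lower, and LDOX, at -1.84 (SE 1.00), did not pass. F3PH fell by 1.396 (SE 0.27), FLS1 by 0.73 (SE 0.17) and CHS by 0.72 (SE 0.19). The list tests gave adjusted p = 0.118 and 0.162 (1.17e-04 and 8.71e-05 on ranks). PAP1 fell by 2.44 (SE 0.79), TT8 by 0.63 (SE 0.34) and MYB11 by 1.06 (SE 0.52), and MYBL2 rose by 1.19 (SE 0.19). HY5 at -0.04 (SE 0.20) did not pass, and PAP2 was untested. Of 15 regulators 5 were higher and 4 lower (adjusted p = 0.955, on ranks 0.985). Of 6 phenylpropanoid genes 2 were higher and 2 lower (adjusted p = 0.928, on ranks 0.833), with 4CL1 at 1.03 (SE 0.22), PAL2 at 0.86 (SE 0.17) and PAL4 at -0.79 (SE 0.41).

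Plastid-encoded transcripts were higher in gun5-1: 49 of 65, with 0 lower (52 adjusted over the list alone), and a median of 1.84. ndhE rose by 3.96 (SE 1.31) and psaB by 2.99 (SE 0.42). psbH was listed at 0 in Col-0, again not read as absence, and at 94.8 FPKM in gun5-1. The planned list test gave the opposite direction, lower, with adjusted p = 0.0133, and adjusted p = 0.234 with the correlation set to 0.05. That test rests on the mean statistic, and trnH had a statistic of -424 with p = 0.757 by the authors' test. On ranks the list was higher with adjusted p = 8.69e-17, and without the 14 genes whose statistic and p disagree it was higher with adjusted p = 6.37e-39. Of 10 mitochondria-encoded genes 1 was higher, ATMG00020 by 0.72 (SE 0.17), with a median of 0.25 (adjusted p = 0.928, on ranks 0.381). Heat-shock genes were lower in 4 of 8 cases (adjusted p = 0.0933, on ranks 0.00211), HSP70 by 2.28 (SE 0.20), HSP90.1 by 2.17 (SE 0.28) and HSP17.8 by 1.88 (SE 0.98). Oxidative stress genes were lower in 10 and higher in 2 of 19 cases (12 and 2 adjusted over the list alone; adjusted p = 0.135, on ranks 0.00428), UPOX at -2.53 (SE 0.19), OXI1 at -1.61 (SE 0.40) and FER1 at -1.36 (SE 0.20).

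Clock genes were higher in 6 of 11 cases in gun5-1 (adjusted p = 0.349, on ranks 0.00112), PRR7 by 1.16 (SE 0.28), GI by 0.96 (SE 0.21) and PRR5 by 0.73 (SE 0.22). Sugar starvation genes were higher in 6 and lower in 1 of 9 cases (adjusted p = 0.616, on ranks 0.136), DIN6 by 0.97 (SE 0.18), STP1 by 0.91 (SE 0.17) and DIN1 by 0.81 (SE 0.19). Plastid chaperones were higher in 6 of 7 cases (adjusted p = 0.162, on ranks 0.00207), CPN60B1 by 1.19 (SE 0.19), and plastid polymerase genes in 6 of 12 with 1 lower (adjusted p = 0.649, on ranks 0.0221, and 0.0556 on ranks with the correlation set to 0.05), PTAC14 by 0.72 (SE 0.32). Glucosinolate genes were lower in 3 of 5 cases (adjusted p = 0.665, on ranks 0.115), MAM3 by 1.36 (SE 0.41). Root markers were lower in 4 of 8 cases (adjusted p = 0.634, on ranks 0.0235), EXPA18 by 0.90 (SE 0.27). Seed genes were lower in 4 and higher in 2 of 14 cases (adjusted p = 0.267, on ranks 0.00279), with SESA2 at -2.03 (SE 0.49), EM6 at -1.74 (SE 0.39) and CRB at 0.94 (SE 0.61). In the jasmonate and salicylate list 1 of 7 was higher and 1 lower (adjusted p = 0.928, on ranks 0.650), ICS1 up by 0.65 (SE 0.32) and JAZ1 at -0.62 (SE 0.36). Over all genes, FBA5 rose by 5.85 (SE 0.65), and FTM1 at -4.50 (SE 0.56), NAC085 at -3.69 (SE 1.07), PP2-B5 at -3.45 (SE 0.61), chr31 at -3.38 (SE 0.40) and NAC103 at -3.01 (SE 0.31) fell most under the same filter. In all, 5471 of 18531 tested genes were called in gun5-1, 3041 higher and 2430 lower, and 914 and 612 changed at least 2-fold.

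**Figure D1:**
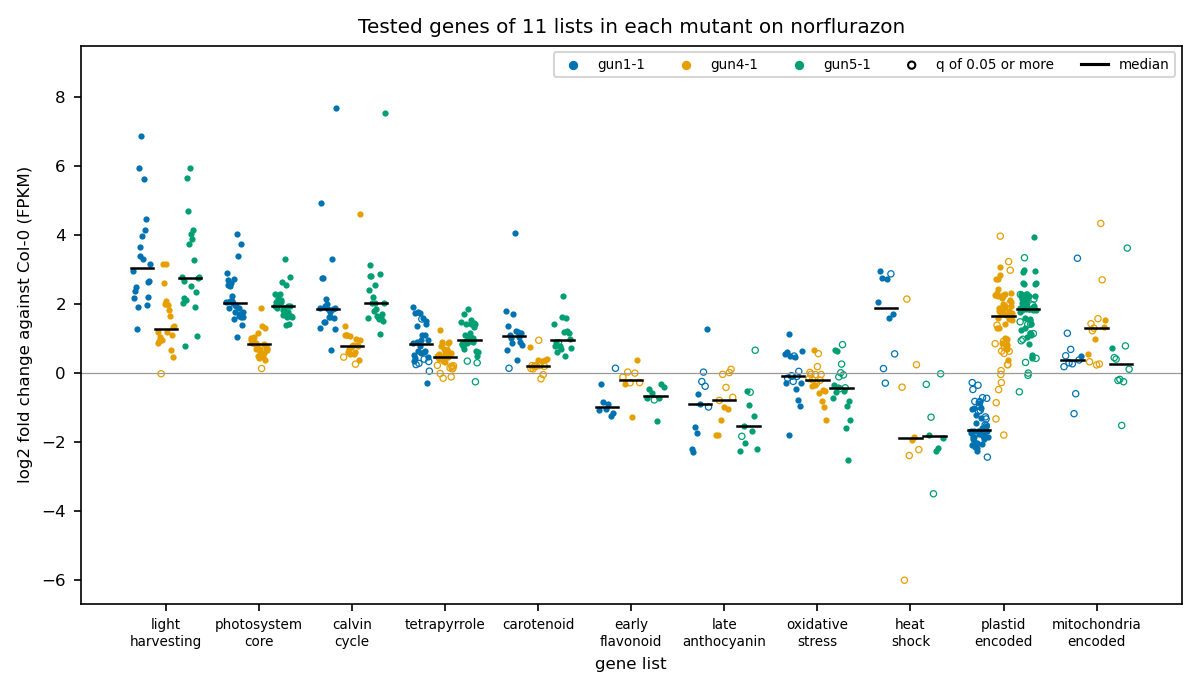
Log2 fold change of group FPKM against Col-0 (vertical axis) for each tested gene with a finite fold change in 11 lists (horizontal axis) in gun1-1, gun4-1 and gun5-1. Filled points passed the authors' q under 0.05, open points did not, and bars are medians. Plastid-encoded genes have medians of -1.67, 1.64 and 1.84, while light-harvesting genes have medians of 3.05, 1.27 and 2.77.

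Differences between the mutants were tested gene by gene from the deposited log2 fold changes and SE. Between gun1-1 and gun4-1, 1143 genes differed at adjusted p under 0.05, 704 of them higher in gun1-1. The plastid genes psaB, psaA, rpoC2 and atpF were lower in gun1-1 by 5.16 (SE 0.95), 5.01 (SE 0.82), 4.58 (SE 0.61) and 4.42 (SE 1.049) on the log2 scale, as was chr31 by 4.81 (SE 0.86). NIT4, a nitrilase, gave 4.56 in gun1-1 and -2.03 in gun4-1, a difference of -6.59 (SE 1.07). M17 differed by -5.00 (SE 0.96), HSP70 by -4.68 (SE 0.26), UGT84A3 by -4.54 (SE 0.51) and SQE6 by -4.35 (SE 1.08), gun4-1 being the lower.

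Between gun1-1 and gun5-1, 313 genes differed, 157 of them higher in gun1-1. Again plastid genes led those lower in gun1-1, psaB by 5.08 (SE 0.96), psaA by 4.75 (SE 0.83), ycf1 by 4.44 (SE 0.25), atpF by 4.39 (SE 1.06) and rpoB by 4.203 (SE 0.38). Heat-shock genes led the other direction: HSP70 differed by -5.01 (SE 0.27), HSP17.6A by -4.55 (SE 0.66), Hsp70-2 by -3.99 (SE 0.37) and HSP90.1 by -3.77 (SE 0.33), with SADHU3-2 at -3.72 (SE 0.65). Between gun4-1 and gun5-1, 511 genes differed, 379 of them higher in gun5-1. NIT4 was higher in gun5-1 by 4.14 (SE 1.09), SESA5 by 3.57 (SE 0.86), FBA5 by 3.48 (SE 1.00), SESA3 by 3.44 (SE 0.69) and CA1 by 2.93 (SE 0.40). SADHU3-2 differed by -2.95 (SE 0.65), chr31 by -2.63 (SE 0.46), NAC010 by -2.32 (SE 0.61), ESE3 by -2.24 (SE 0.39) and TIM17-1 by -2.07 (SE 0.57), gun5-1 being the lower. These counts rest on the conservative SE described with the methods.

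**Figure D2:**
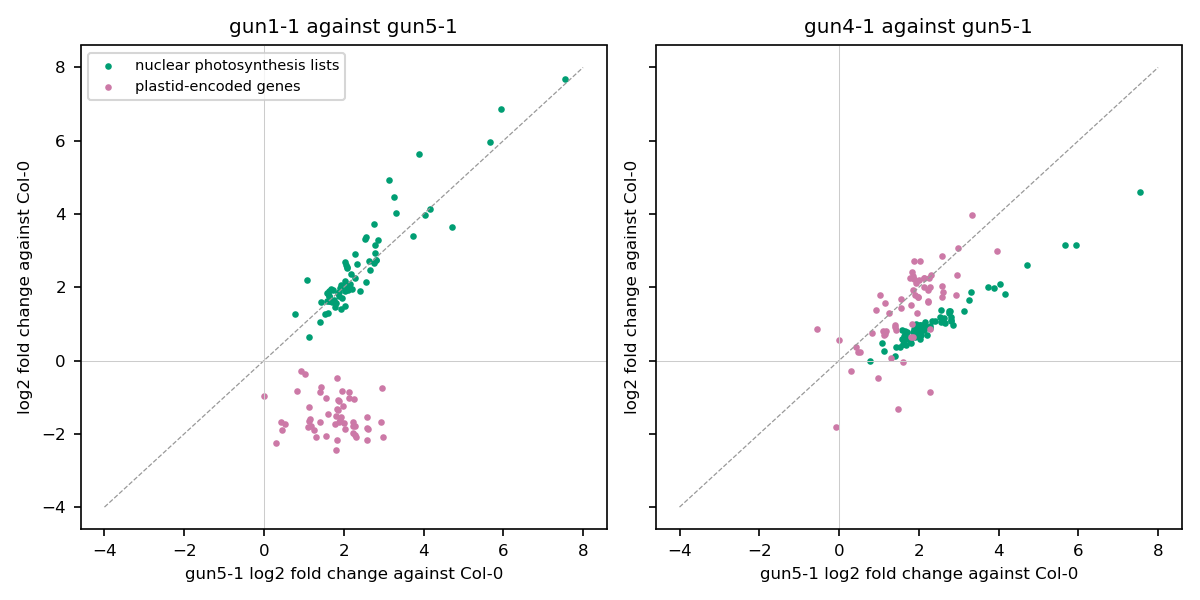
Log2 fold change against Col-0 in gun1-1 (left) and gun4-1 (right), vertical axes, against that in gun5-1, horizontal axes, for genes of the light-harvesting, photosystem and Calvin cycle lists and for plastid-encoded genes; the dashed line marks equal values. Lines through 0 have slopes of 1.06 (nuclear) and -0.77 (plastid) for gun1-1, and 0.47 and 0.82 for gun4-1.

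Calls overlapped between mutants in the same direction more than independent lists would. Of genes tested in both, gun1-1 and gun5-1 shared 1984 higher and 1404 lower genes, where independent lists give 575 and 369, and 234 were called in opposite directions (921 for independent lists). For gun4-1 and gun5-1 the shared counts were 976 and 660 (250 and 148 for independent lists), with 122 opposite (385). For gun1-1 and gun4-1 they were 735 and 528 (286 and 169), with 391 opposite (440), 267 of them lower in gun1-1 and higher in gun4-1. In all 3 mutants, 680 genes were higher and 440 lower. All 3 tables share the Col-0 libraries, which raises shared calls by an amount that was not measured: unchanged mutants simulated with shared controls gave 0 shared calls, which does not gauge it. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.72 (gun1-1 and gun5-1), 0.58 (gun4-1 and gun5-1) and 0.36 (gun1-1 and gun4-1), and simulated shared controls alone gave 0.45, 0.42 and 0.43. The covariances were 0.243, 0.116 and 0.0746, against 0.0284, 0.0277 and 0.0264 simulated.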

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

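The tests of differences between mutants in this part, and all tests of explanations, were chosen after the results were seen. Each value below is a difference between 2 mutants in their change from Col-0. Such tests covered the genes named by the rules fixed in advance and the 10 more named in the closing part for differing. Of 401 tests 124 passed, 52 of them with changes of opposite sign. Genes named for large changes or for differing are among them, so these counts are not a rate of difference. The passing tests of the 3 mutated genes and of the 12 genes fixed individually are given here, with all lists that passed.

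Plastid-encoded genes were lower in gun1-1 than in gun4-1 (adjusted p = 5.99e-93) and gun5-1 (2.60e-204). On ranks with a correlation of 0.05 these were 3.82e-09 and 3.46e-09. Plastid-encoded genes were higher in gun5-1 than in gun4-1 (0.0115, but 0.140 with a correlation of 0.05). Library selection with oligo(dT) takes up RNA without long tails by carry-over, which would move mitochondria-encoded transcripts too. Their median was 0.38 in gun1-1 (bootstrap 95% range over genes, not libraries, 0.18 to 0.68, 11 genes). The plastid median was -1.67, and the opposite signs argue against carry-over there. In gun5-1 their median was 0.25 (-0.22 to 0.72, 10 genes) against 1.84. Changes of these 10 genes ran from -1.52 to 3.62, and the 1 called, ATMG00020, rose by 0.72 (SE 0.17). The gun5-1 values argue against carry-over as the sole source but leave a part of it open. In gun4-1 the mitochondrial median was 1.2997 (bootstrap 95% range 0.56 to 1.54) against 1.64, so carry-over and a change of plastid transcripts cannot be told apart there. Plastid DNA would add about equal FPKM to every gene, but the 90th and 10th percentiles of the gain in gun5-1 differed 78.7-fold among 40 loci of 500 bases or more. The gain was thus unequal, but short genes with unstable values may be among these loci. The ratio therefore does not settle whether DNA was the sole source of the rise in gun5-1. In gun4-1 DNA was not tested. Loci of that length had a median of -1.69 in gun1-1. A locus spans all transcripts that overlap at a place, so short genes may remain among them. Unstable values of short genes are therefore not ruled out. An effect of the genotype may remain, as a hypothesis.

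Heat-shock genes were higher in gun1-1 than in gun4-1 (5.12e-22) and gun5-1 (2.47e-46). On ranks with a correlation of 0.05 these were 0.00131 and 7.17e-04. The authors' scaling would move all genes alike. The mean of the tested heat-shock genes with a finite change was weighted by their standard errors, taking genes as independent. It lay from the median of all other tested genes by 2.143 in gun1-1 (SE 0.098) and -1.67 in gun5-1 (SE 0.13). In gun4-1 it lay by -1.42 (SE 0.13, 8 of 9 genes, the other listed at 0 in gun4-1 and not called). The list was flagged for differing against all other genes, so a gap from their median was largely set in advance. These values are therefore no separate test of scaling. Without HSP70 and HSP90.1 the values were 1.99 (SE 0.16), -0.24 (SE 0.24) and -0.60 (SE 0.23), so that gun4-1 rests on these 2 genes and gun5-1 largely on them. In gun4-1 the gap of the unweighted median had a bootstrap 95% range of -2.40 to 0.24, and the other heat-shock genes are not shown to be lower there. A difference in handling or temperature between the groups cannot be told apart from genotype, since only group values exist, with a median of 1.88 in gun1-1.

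The changes of light harvesting (9.43e-58 against gun1-1, 2.55e-73 against gun5-1), photosystems (3.96e-49, 6.22e-64), Calvin cycle (4.60e-32, 2.14e-56), tetrapyrroles (2.88e-04, 2.65e-11), carotenoids (8.17e-07, 6.40e-11), chloroplast regulators (3.50e-07, 6.19e-07) and plastid chaperones (5.03e-04, 0.0025) were smaller in gun4-1 than in the other 2 mutants. On ranks with a correlation of 0.05 light harvesting gave 3.29e-07 against either mutant. Each of these lists passed in all 4 versions of the test, the highest adjusted p being 0.0119 (tetrapyrroles against gun1-1). Fewer genes were called in gun4-1 than in gun5-1. The median SE in gun4-1 was 0.977 times that in gun5-1, which argues against lower precision. The slope on gun5-1 was 0.82 (bootstrap 95% range 0.71 to 0.91) for plastid-encoded genes and 0.47 (0.43 to 0.51) for nuclear photosynthesis genes. These ranges do not overlap. They come from resampling genes, not libraries, and both changes share the Col-0 libraries. The ranges therefore do not show a difference between plastid and nuclear genes beyond replicate spread. Carry-over was also left open for the plastid rise in gun4-1. Other nuclear lists had similar slopes, 0.47 for tetrapyrroles and 0.46 for oxidative stress, or differed more, 0.28 for carotenoids and 0.61 for late anthocyanin genes. Clock genes had -0.31 (-0.54 to -0.03, also over genes). This sign is opposite to that of a uniformly smaller response, but the range holds no replicate spread. The seed slope was 1.73 (1.09 to 2.46), but the seed difference missed on z values (adjusted p = 0.0600, on ranks 0.0458). An effect of the gun4-1 allele that differs between gene groups may remain, untested.

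These list differences passed in all 4 versions of the test (z values or ranks, correlation of 0.01 or 0.05). Early flavonoid genes were lower in gun5-1 than in gun4-1 (0.00177), phenylpropanoid genes were lower in gun1-1 than in gun5-1 (0.00543), and plastid polymerase genes were higher in gun5-1 than in gun1-1 (0.0108). Oxidative stress genes were lower in gun5-1 than in gun1-1 (2.19e-05), clock genes were lower in gun4-1 than in gun5-1 (2.74e-06), and glucosinolate genes were lower in gun5-1 than in gun4-1 (0.00705).

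Other list differences passed on z values with a correlation of 0.01 and were lost in at least 1 other version, whose highest adjusted p follows each. Clock genes were lower in gun4-1 than in gun1-1 (0.0338, highest 0.241), oxidative stress genes were lower in gun5-1 than in gun4-1 (0.0385, highest 0.250), and photosystem genes were lower in gun5-1 than in gun1-1 (0.0338, highest 0.224); each of these 3 failed in all other versions. Light-harvesting genes were lower in gun5-1 than in gun1-1 (0.00705, highest 0.162). Early flavonoid genes (0.00136, highest 0.162) and phenylpropanoid genes (0.0198, highest 0.160) were lower in gun1-1 than in gun4-1. Late anthocyanin genes were lower in gun5-1 than in gun4-1 (0.0327, highest 0.0827). Sugar starvation genes were higher in gun5-1 than in gun1-1 (0.00705, highest 0.175) and gun4-1 (6.08e-04, highest 0.127), and neither passed on ranks. Mitochondria-encoded genes were higher in gun4-1 than in gun1-1 (0.0385, highest 0.0961) and gun5-1 (0.00705, highest 0.113).

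Of single genes, the change in gun4-1 minus that in gun1-1 was -1.04 for LHCB1.2, -1.41 for HEMA1, -1.098 for MYBL2, -1.77 for GLK1, -1.76 for TT8, -1.06 for CHLH and 0.96 for CHS. TT8 was called higher in gun1-1 and lower in gun4-1. The change in gun5-1 minus that in gun1-1 was 1.06 for LHCB1.2 and 0.80 for GUN1. The change in gun5-1 minus that in gun4-1 was 2.11 for LHCB1.2, 0.97 for HEMA1, 1.33 for MYBL2 and 1.16 for CHLH.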

How the results depend on the processing

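Tests on ranks, without disagreeing statistics, on normal p of the statistic, over 1 transcript per gene, on summed FPKM and with SE divided by the calibration factor were chosen after the data were seen. No paired analysis was possible because the tables hold group values only, and for the same reason leave-one-out and the replicate block were not run and depth limits are unknown. Every tested gene had more than 1 FPKM in a group, so that filter removed none. Counts of called genes stayed within 1.5 times under q under 0.01 and adjustment over 1 transcript per gene. Median centring shifted the tables by -0.0076, 0.0036 and -0.0039, too little to test the scaling. With a log2 fold change of at least 1 they were 1761, 577 and 1526 in gun1-1, gun4-1 and gun5-1, with a log2(FPKM + 1) difference of at least 1 they were 2178, 1055 and 1914, and by the normal p of the statistic 2864, 594 and 2406; stricter criteria alone lower the first. With the fold minimum, shared calls were 218 (gun1-1 and gun4-1), 791 (gun1-1 and gun5-1) and 289 (gun4-1 and gun5-1). With SE divided by the calibration factor, 4248, 2044 and 2606 genes differed between these pairs, and 310 differed between gun4-1 and gun5-1 at adjusted p under 0.01.

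The planned list test called 5, 4 and 6 lists. With a correlation of 0.05 it called 3 in gun1-1, 2 in gun4-1 and 5 in gun5-1. With the pseudocount it called 12, 9 and 14, on ranks 13, 12 and 16, on ranks with a correlation of 0.05 13, 12 and 15, and without disagreeing statistics 12, 11 and 14. The plastid-encoded list in gun5-1 reversed from lower to higher with the pseudocount (adjusted p = 5.00e-61), on ranks (8.69e-17), on ranks with 0.05 (2.49e-07) and without disagreeing statistics (6.37e-39). Lists that passed in neither setting also changed sign: flavonoid regulators with the pseudocount in gun1-1 (0.978) and gun5-1 (0.744), and phenylpropanoid genes in gun5-1 on ranks (0.833) and on ranks with 0.05 (0.848). Among 218 values of named genes, 27 no longer passed at q under 0.01 and 73 with the fold minimum, 1 more passed after median centring, 24 moved with log2(FPKM + 1), 2 moved with summed FPKM of all transcripts, and none reversed under the alternatives run.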

Other observations

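The gene groups in this part were chosen after their values were seen, and their tests are on ranks of the authors' statistics. The 4 ferritin genes, which store iron, were all higher in gun1-1 (adjusted p = 0.00339), while in gun4-1 and gun5-1 2 of the 4 were lower and none was higher (adjusted p = 0.0112 and 0.0193). By the authors' deposited table, FER1 went from 999 to 1537 FPKM in gun1-1, from 1073 to 415 in gun4-1 and from 983 to 382 in gun5-1. FER3 rose by 0.83 in gun1-1 and fell by 0.84 in gun4-1 and 0.68 in gun5-1.

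A group of 11 genes known to respond to disturbed mitochondria was lower in all 3 mutants: 8 lower and 1 higher in gun1-1 (adjusted p = 0.00339), 8 lower in gun4-1 (1.07e-04) and 11 lower in gun5-1 (1.54e-06). The log2 fold changes in gun1-1, gun4-1 and gun5-1 were -0.95, -0.99 and -2.53 for UPOX, -1.01, -0.39 and -0.97 for CRF6, and -5.42, -0.72 and -2.79 for TIM17-1. UGT74E2 rose by 2.66 in gun1-1 and fell by 0.66 and 0.64 in the others. AOX1A, the alternative oxidase, gave 0.04 in gun1-1, where it did not pass, and fell by 0.49 and 0.97. The group was picked from these values, so its tests are not independent evidence.

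Of 160 process terms from the reference annotation, tested on ranks with a correlation of 0.05 and adjusted over 480 tests, photosynthesis, electron transport in photosystem I, chlorophyll biosynthesis and the responses to red, far-red and blue light were higher in all 3 mutants. Cell wall organization was lower in gun1-1, 11 of 20 genes (adjusted p = 0.0217), and in gun5-1, 12 of 20 (0.0178). It was the sole term lower in those mutants, and no term was lower in gun4-1. Chloroplast organization was higher in gun5-1, 21 of 30 genes (adjusted p = 0.00765).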
